A study of Mus musculus with 2 samples.

How the data were processed

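Newborn mouse forebrain RNA from 2 pups was taken to libraries from 13 pg, with RNA extraction by the mirVana method and a Smart-seq protocol, per the labels. Each library comes with a table per gene and a table per transcript, not pooled. The authors deposited expected counts, which are estimated reads with multi-mapped reads shared out between features, per the file headers, whose column names are those RSEM writes. The deposited TPM has the same total in each library, over all listed features, spike-ins and mitochondrial genes included, and a posterior mean TPM with credibility bounds stands beside it. The deposited FPKM is reads scaled by effective length and by library total, per the file headers. The deposited percent of a gene's TPM in each transcript was not read; isoform shares were computed from transcript TPM. The aligner, the counter, their versions, the strand setting and the amounts of spike-in added are not given in the sources used here. Text deposited with each library names assembly mm10 and annotation M4.

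Each gene table lists 69691 features: 43346 genes, 97 spike-in entries (96 ERCC and 1 phiX, which had 0 reads) and 26248 short entries of 61 to 259 bases with numeric names and 0 reads, which were left out because nothing states what they are. Symbols, biotypes and positions came from GENCODE M21, which is on the same assembly, by gene identifier without version; 42462 genes (98.0%) matched, and the unmatched held 0.154% of TPM in pup 1 and 0.151% in pup 3. Of 425 symbols in the lists, 421 matched, and Ahsp, Rn45s, Snhg1 and Sox2ot did not. Where a symbol had more than 1 identifier, the lower was used.

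The 2 libraries form 1 group and are separate pups per the labels, although the labels give both the same donor identifier. No test between pups is possible with 1 library each, so no p-value is given. A gene was called found at TPM of 1 or more. Agreement was computed on log2(TPM + 1), with 200 resamples of genes for the intervals, and log2 ratios understate the change of low genes for that reason. Dispersion was estimated with edgeR 4.0.16 on expected counts rounded to whole numbers, with an intercept, TMM factors (0.919 and 1.09) and genes of 10 or more reads in total (11993 genes), with 30 resamples of genes for its interval. The 32 gene lists were fixed before the data were examined. The level of a list was ranked as the percentile of its median log2(TPM + 1) among 10000 random lists of protein-coding genes of the same size. Its difference, over members above 0 TPM in either pup, was ranked as the percentile of the median log2 ratio among 10000 lists in which each member was replaced by 1 of the 100 protein-coding genes nearest in mean level, also for non-coding lists. Lists outside the 2.5th to 97.5th percentiles were called. Random lists tied with a list were counted in part as lower, so a list with a median of 0 TPM does not rank at 0. No fold is given against 0 reads. Medians of lists were also taken over plain log2 ratios without a pseudocount, with 0 reads set to 3 reads in that library, converted to TPM with the gene's effective length; where the middle member is such a gene, the median is a bound. Tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and DESeq2 1.42.0 for an alternative size factor.

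The genes named are, by a rule fixed before the data were examined: the 10 nuclear protein-coding genes with the highest mean TPM; the 3 highest members of each list, with members of non-neural or other-tissue lists at 10 TPM or more in either pup; the 6 largest and 6 smallest log2 ratios among nuclear protein-coding genes at mean TPM of 50 or more; all sex chromosome genes; and isoform genes at mean TPM of 20 or more. Some genes that the rule takes are not reported here. Drd1, Drd2, Eno2, Slc2a3, Pgk1 and ERCC-00074 were chosen after their values were seen.

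Steps were tested on simulated data with known answers, and the list step on random lists of the real genes. Coefficients of variation of 0.3 and 1 were recovered as 0.299 and 0.975 over 43346 genes. The value estimated from the data, 2.07, lies above these, and recovery at that size was not tested. Of 200 random lists of 13 genes with their measured ratios, 4.0% lay outside the central 95%. A share near 5% is fixed by construction, since the lists were ranked against the same genes. It does not cover lists whose members vary together. After a shift by log2 -2, 64.5% of these lists were called, over 11415 genes, so smaller shifts can be missed. A correlation of 0.6 was recovered as 0.600 over 10000 simulated genes, none of which was missing from a library. Alternatives covered the detection threshold, the pseudocount, a filter on low values, FPKM, CPM, posterior mean TPM, rescaling without spike-ins and mitochondrial genes, matching on length, thinning of reads and each pup alone. Detection by the level in the other pup, agreement over genes found in both pups and the structural RNA list with near-identical copies counted once were added after the data were seen. Over the same 2818 genes, found in both pups and at mean TPM of 50 or more, the median log2 ratio was 0.14 on TPM, 0.12 on CPM, 0.20 on rescaled TPM and 0.40 on FPKM; list differences are ranked relative to other genes.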

Results

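RNA was measured in the forebrain of newborn mice of strain B6NCrl at an input of 1 cell-equivalent, 13 pg, of RNA longer than 200 nt. Although the assay is catalogued as single-cell sequencing, the material was RNA extracted from whole forebrain tissue, so each library sampled a mixture of all forebrain cell types and not 1 cell. There were 2 libraries, each from the forebrain of a different pup at postnatal day 0, called pup 1 (replicate 1) and pup 3 (replicate 2). Both belong to 1 group, so the design implies no contrast between conditions. It allows a description of which transcripts were found at this input and how far they differed between 2 animals. With 1 library per pup, differences between pups were not tested and biological and technical spread are not separated. The deposited expected counts summed to 41082811 in pup 1 and 29881397 in pup 3. Levels below are TPM, transcript abundances scaled to the same total in each library, given as the mean ± SD of the 2 pups (n = 2) or for each pup in turn.

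The most abundant nuclear protein-coding transcript was Tuba1a, the neuronal alpha-tubulin gene (ENSMUSG00000072235, mm10 chromosome 15, 98949837 to 98953703), at 28363 ± 2714 TPM. It was followed by Stmn1, a microtubule-destabilising protein, at 7373 ± 1926 TPM, and by the cytoplasmic actin Actb at 6686 ± 1472 TPM. The other members of the 10 highest were Ubb (6337 ± 1907), Eef1a1 (5033 ± 2322), Ftl1 (4997 ± 563), Actg1 (4714 ± 1721), Tmsb4x (4435 ± 3009), Ppia (4298 ± 1945) and Tubb3 (4073 ± 3113 TPM). The neuronal beta-tubulin Tubb3 (ENSMUSG00000062380) differed most in the direction of pup 1 among these, at 6275 TPM in pup 1 and 1872 TPM in pup 3. Tmsb4x, an actin-binding peptide, lay the other way, at 2308 and 6563 TPM. Protein-coding genes held 84.7% of TPM in pup 1 and 82.4% in pup 3. That total includes spike-ins, which were higher in pup 3, so these shares do not describe forebrain RNA alone.

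Genes found at TPM of 1 or more numbered 10096 in pup 1 and 6960 in pup 3, a ratio of 1.45. Of the 11215 genes found in either pup, 5841 were found in both (52.1%, 95% Clopper-Pearson interval 51.2 to 53.0), 4255 in pup 1 alone and 1119 in pup 3 alone. By mean level, the share found in both was 16.3% at 1 to 5 TPM, 22.3% at 5 to 10, 53.0% at 10 to 50, 91.3% at 50 to 100 and 99.1% at 100 TPM or more. All 287 genes at 500 TPM or more in pup 1 were found in pup 3, and all 328 at that level in pup 3 were found in pup 1. Of genes at 10 to 50 TPM in pup 1, 50.3% (48.8 to 51.8) were found in pup 3, against 79.4% (77.8 to 81.0) in the opposite direction. The number of nuclear protein-coding genes at 50 TPM or more was nearly equal, 2950 in pup 1 and 2947 in pup 3. The Clopper-Pearson intervals on shares of genes take genes as independent trials. They do not cover read-counting error or the spread between animals. The floor of 3 reads is 0.0730 CPM in pup 1 and 0.1004 CPM in pup 3. This floor and intervals on reads cover counting error only, since reads without molecular identifiers are not independent molecules.

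**Figure D1:**
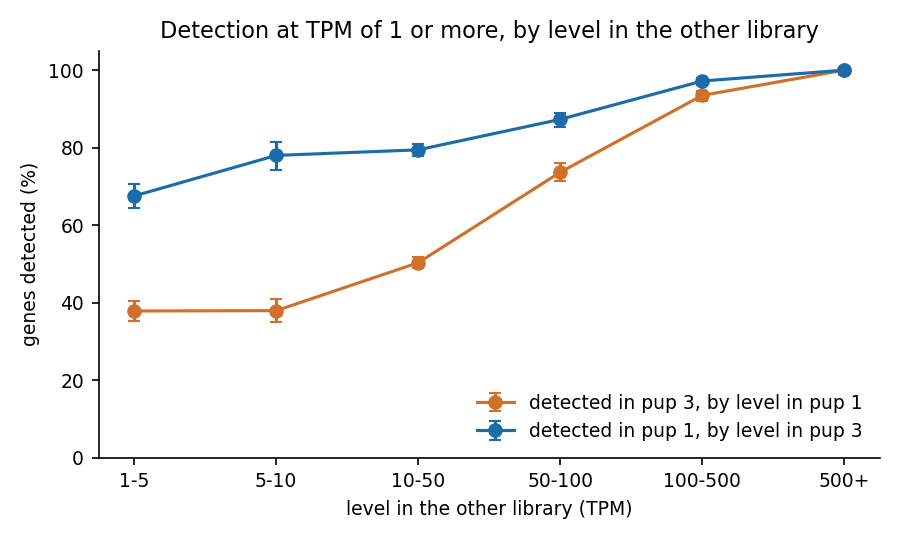
Percent of genes found at TPM of 1 or more in one pup (y axis) by their level in the other pup in TPM (x axis), with 95% Clopper-Pearson intervals as bars. At 10 to 50 TPM the share was 50.3% in pup 3 and 79.4% in pup 1, and at 500 TPM or more it was 100% in both.

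Across the 13893 genes with any signal, Pearson's r of log2(TPM + 1) between the pups was 0.571 (0.559 to 0.584 from resampled genes) and Spearman's rho was 0.455. These are correlations across genes, which are not independent replicates. Among the 2947 genes at mean TPM of 50 or more, the SD of the log2 ratio was 2.04 and 57.6% lay within 2-fold. The root-mean-square coefficient of variation was 110% at 10 to 50 TPM, 73.6% at 50 to 100 TPM, 53.2% at 100 to 500 TPM and 39.4% at 1000 TPM or more. The common biological coefficient of variation from edgeR was 2.07, and 0.856 over the 6367 genes with 10 or more reads in each library. The 2 libraries differed by more than read-counting noise (chi-square per degree of freedom 1217 over 11984 genes), a check that covers counting error only.

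The genes farthest apart were seen in one pup and nearly or wholly missing from the other. Nudt2, which cleaves diadenosine tetraphosphate, stood at 198 TPM in pup 3 with 0 reads in pup 1. Rd3l and Cmc2 were at 144 and 140.4 TPM in pup 3, also with 0 reads in pup 1. Mettl22 (312 TPM), the nucleotide synthesis enzyme gene Prps1 (176 TPM) and Rgs19 (167 TPM) completed that end, each with 1 to 4 reads in pup 1. At the other end, Tmx2 reached 407 TPM, Dlgap4 348 TPM, Sft2d1 270 TPM, the glutathione transferase gene Gstm1 259 TPM and Psmd13 256 TPM in pup 1, each with 0 reads in pup 3. The deposited upper credibility bounds in pup 3 were 0.667 TPM for Tmx2, 0.933 for Dlgap4, 1.37 for Sft2d1, 0.368 for Gstm1 and 6.21 for Psmd13. Tmed9 had 259 TPM in pup 1 and 2 reads in pup 3. Of the 2797 nuclear protein-coding genes at mean TPM of 50 or more, 56 had 0 reads in pup 3 and 11 had 0 reads in pup 1.

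The pan-neuronal list had 15 of 16 members in both pups and a median of 128 TPM, at the 100th percentile of 10000 random lists of protein-coding genes. Within it the growth-cone protein gene Gap43 was at 1878 ± 515 TPM and Stmn2 at 1762 ± 33.8 TPM. Of the cortical excitatory list 11 of 17 members were in both pups (percentile 97.9), led by the transcription factor Neurod6 at 364 ± 130.1 TPM, Mef2c at 116 ± 41.5 and Cux1 at 35.0 ± 8.29 TPM. The striatal list (97.6) had 5 of 14 members in both pups, 1 in pup 1 alone, 3 in pup 3 alone and 5 in neither, the dopamine receptor genes Drd1 and Drd2 having 0 reads in both. It was led by the opioid precursor Penk at 156 ± 58.7, Tac1 at 122 ± 18.5 and Meis2 at 107 ± 1.85 TPM. The GABAergic list, at percentile 95.4 with 7 of 16 members in both pups, held the neuropeptide genes Npy (547 ± 352 TPM) and Sst (411 ± 45.2) and the GABA-synthesising enzyme gene Gad1 (202 ± 85.9 TPM). Telencephalic transcription factors stood at percentile 97.8 with 5 of 12 members in both pups, among them Bcl11a at 79.1 ± 16.3 TPM and Zbtb20 at 69.9 TPM in pup 1 and 5.14 TPM in pup 3. The pups were closer in reads of Zbtb20, 12312 in pup 1 and 3195 in pup 3. The striatal list was at percentile 96.3 on CPM and 62.3 without replicate 2, and the telencephalic list at 95.7 on CPM and 89.8 without replicate 1.

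Of the 17 genes of the hindbrain and posterior body axis list, mainly Hox genes, 0 reached TPM of 1 in either pup (percentile 19.4). The list's median was 0 TPM, so this percentile comes from ties with random lists and is the lowest rank possible. Hoxa2 had 1 read in pup 1, and Hoxa4 and Hoxc8 had 0 reads in both. Of 13 thalamic and hypothalamic genes (percentile 73.3), 1 was found in both pups, 5 in pup 1 alone and 1 in pup 3 alone. Tcf7l2 was found in both pups at 101 ± 35.7 TPM, Lhx9 at 40.5 TPM in pup 1 alone and the vasopressin gene Avp at 44.4 TPM in pup 3 alone.

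Progenitor and glial transcripts were also present. Fabp7, a fatty acid binding protein of radial glia, was at 1813 ± 674 TPM, Vim at 276 ± 146 and Mfge8 at 176 ± 21.6 TPM, in a radial glia list at percentile 90.5, with 98.1 without replicate 1. The astrocyte list was at percentile 99.98 with 11 of 12 members in both pups, including the lipid carrier gene Apoe at 1177 ± 7.46, Id3 at 329 ± 34.1 and Aldoc at 257 ± 90.8 TPM. Intermediate progenitor genes (80.0) were each found in 1 pup or neither: Neurod1 at 40.6 and Sstr2 at 34.3 TPM in pup 1, and Mfng at 99.0 TPM in pup 3. The oligodendrocyte lineage list (81.6) had 2 of 12 members in both pups; Pdgfra was at 16.4 ± 2.21 TPM, Cnp at 34.0 and 2.59 TPM, and Olig1 at 40.7 TPM in pup 1 with 0 reads in pup 3.

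Markers of non-neural cells were found in both libraries. The choroid plexus product Ttr was at 1811 ± 123 TPM and the prostaglandin D synthase gene Ptgds at 1795 ± 64.2 TPM. Globin transcripts included Hba-a2 at 1098 ± 573, Hbb-bs at 637 ± 254, Hba-a1 at 550.1 ± 278 and Hbb-bt at 206 ± 19.5 TPM, beside the erythroid heme enzyme gene Alas2 at 22.3 ± 6.80 TPM; the globin copies share reads, so their split is uncertain. The erythroid, meningeal and choroid plexus lists were at percentiles 96.4, 94.6 and 36.6. Other meningeal genes were Igf2 at 96.6 ± 83.0, Col3a1 at 54.1 ± 32.2, Dcn at 51.2 ± 25.2 and Col1a2 at 10.9 ± 0.495 TPM, with Slc6a13 at 42.6 TPM in pup 1 and 0.02 TPM in pup 3. Choroid plexus genes beyond Ttr were Enpp2 at 44.5 and 106 TPM in pups 1 and 3, and Folr1 (85.3 TPM), Tmem212 (24.4 TPM) and Foxj1 (11.8 TPM) in pup 1, each with 0 reads in pup 3.

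Microglial genes (percentile 93.8, with 97.9 without replicate 2 and 39.3 without replicate 1) differed in which members were seen. The value of 39.3 is the lowest rank that ties allow, as the list's median in pup 3 was 0 TPM. The complement gene C1qb was at 104 and 64.4 TPM, C1qa at 76.2 TPM in pup 1 alone and C1qc at 49.1 TPM in pup 3 alone. Csf1r (34.5 TPM), Tyrobp (32.7 TPM), Fcrls (23.3 TPM) and Aif1 (21.03 TPM) had reads in pup 1 and 0 reads in pup 3. In the endothelial and mural list (85.3), the tight-junction gene Cldn5 was at 41.8 and 82.2 TPM, Ly6c1 at 13.8 and 54.5, Esam at 1.39 and 71.9, and Rgs5 at 4.15 and 15.1 TPM. The glucose transporter gene Slc2a1 was at 84.8 TPM in pup 3 with 0 reads in pup 1, while the pericyte gene Pdgfrb was at 26.9 TPM in pup 1 with 0 reads in pup 3.

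Among processes, axon growth genes were very abundant (percentile 100, all 17 members in both pups), Tmsb10 reaching 2946 ± 1237 TPM. Presynaptic genes (100) included Rab3a at 316 ± 112 and Cplx1 at 251 ± 151 TPM. Postsynaptic and glutamate receptor genes (96.7, with 99.25 on CPM and 98.7 without replicate 1) were led by Camk2b at 127 ± 97.9, Gria2 at 126 ± 97.9 and Nlgn1 at 53.6 ± 35.8 TPM. Nlgn1 was higher in pup 3 in TPM but had more reads in pup 1, 8198 against 5847. GABA receptor genes (98.8) included Gabra3 at 47.6 ± 8.85 TPM. Cell cycle genes (99.8) included Pcna at 93.8 ± 5.18, the cyclin gene Ccnd2 at 81.4 ± 1.87 and Mcm6 at 56.8 ± 6.55 TPM, although 9 of 18 members were found in pup 1 alone and the percentile without replicate 1 was 90.1. Heat shock genes (100) included Hspa8 at 3201 ± 1078, Hsp90ab1 at 1529 ± 111 and Hsp90aa1 at 901 ± 374 TPM. In reads Hsp90ab1 was farther apart, 96293 in pup 1 and 38400 in pup 3. Immediate early genes (20.8) were mostly missing, with 8 of 11 found in neither pup; Jun was at 25.2 and 3.28 TPM, Nr4a1 at 24.5 TPM in pup 3 alone and Dusp1 at 1.30 TPM in pup 1 alone. Imprinted genes (99.5) included Nnat at 2786 ± 1643, Ndn at 1394 and 1246 TPM in pups 1 and 3, and Snrpn at 957 ± 146 TPM.

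Mitochondrially encoded transcripts (percentile 100) were led by mt-Atp8 at 11807 ± 2064, mt-Atp6 at 9804 ± 3524 and mt-Nd1 at 6479 ± 813 TPM; their reads can be shared with nuclear copies, so single values are uncertain. The long non-coding list (99.99) was led by Malat1 at 1494 ± 1110, the small nucleolar RNA host Gas5 at 424 ± 187 and Meg3 at 419 ± 299 TPM. Histone genes, whose replication-dependent messages lack poly(A) tails, were at percentile 58.9, with Hist1h4d at 183 ± 66.0 TPM and Hist1h1e (40.7 TPM) and Hist1h4i (31.3 TPM) in pup 1 with 0 reads in pup 3. The structural RNA list was at percentile 70.7.

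Many of these level percentiles depended on which genes entered. With only members and genes at mean TPM of 1 or more, 6 lists fell back inside the central 95%: cell cycle (80.5), striatal (78.6), GABA receptor (77.1), imprinted (64.8), telencephalic (64.2) and cortical excitatory genes (19.3). Under the same filter the GABAergic list lay at 34.3, microglial genes at 29.7, histone genes at 28.0, intermediate progenitor genes at 22.0, radial glia at 21.01, glutamate receptor genes at 19.95, the oligodendrocyte lineage at 17.7, thalamic and hypothalamic genes at 15.1, Cajal-Retzius genes at 8.53 and sex chromosome genes at 5.60. Erythroid (100), structural RNA (99.9) and choroid plexus genes (79.1) lay higher than without it. Without replicate 1, intermediate progenitor genes were at percentile 41.8, Cajal-Retzius genes at 41.7, endothelial genes at 39.8, and thalamic and hypothalamic genes at 43.7, the last being at 24.6 without replicate 2. The structural RNA list was at 17.6 without replicate 2. On posterior mean TPM the hindbrain and immediate early lists were at 0.08 and 0.11, below the central 95%, and without replicate 1 at 45.3 and 43.1. Each list just given without replicate 1 had a median of 0 TPM in pup 3. Those percentiles come from ties with random lists and are the lowest possible, not middle ranks. The same holds for the values just given without replicate 2, and for the hindbrain and immediate early lists in the main result (19.4 and 20.8).

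**Figure D2:**
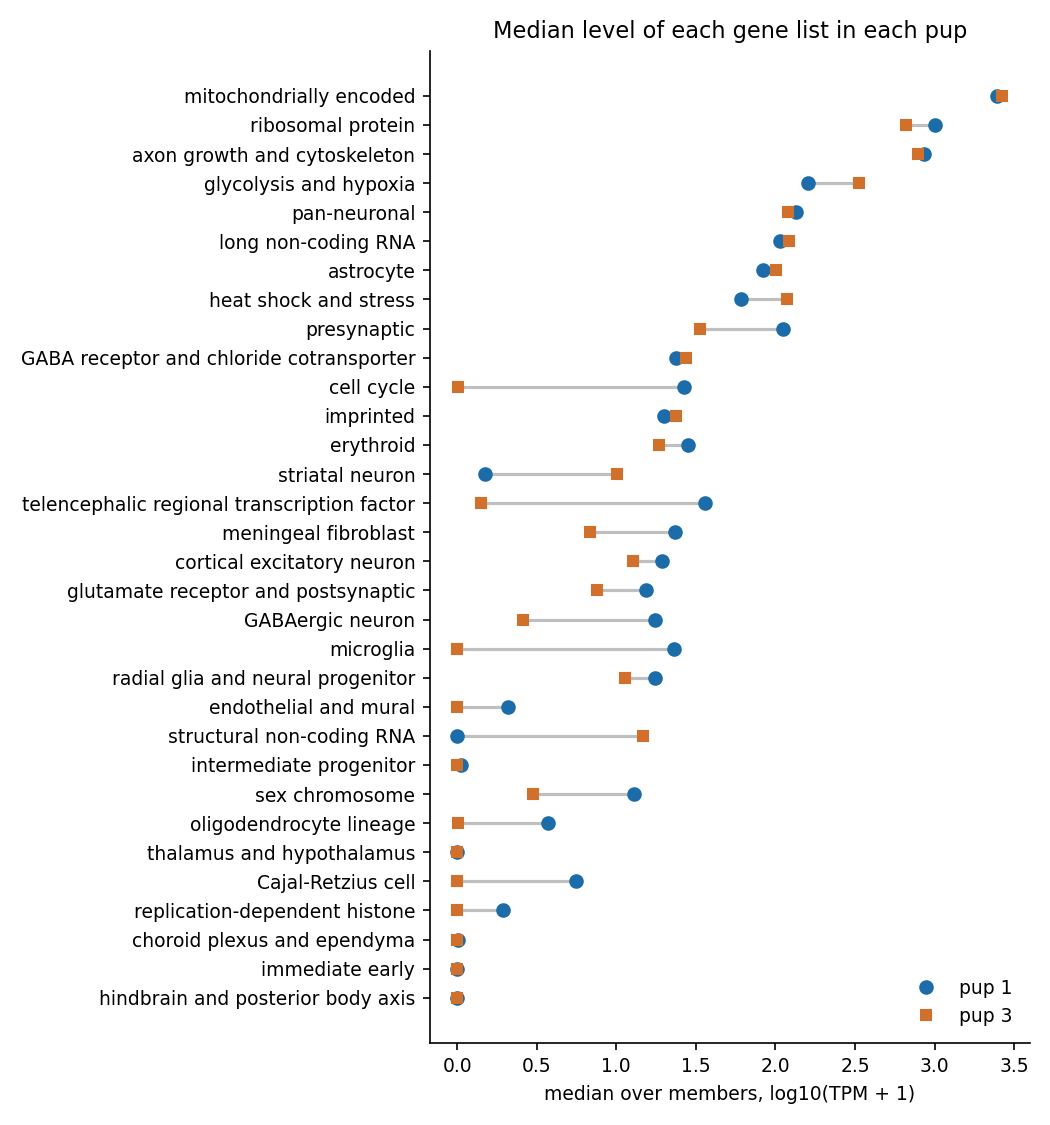
Median over the members of each gene list in pup 1 (circles) and pup 3 (squares), as log10(TPM + 1) on the x axis, with 1 row per list ordered by the mean. Mitochondrially encoded, ribosomal protein and axon growth lists stand highest. The hindbrain, immediate early, and thalamus and hypothalamus lists are at 0 in both pups.

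Genes of the glycolysis and hypoxia list, called the glycolysis list for short, were lower in pup 3 than other genes of their level. Not all of its members encode glycolytic enzymes, since it also holds Vegfa, Bnip3 and Slc2a3. The list itself was abundant, at level percentile 100. Of 13 members, 10 were higher in pup 1 and 3 in pup 3, and the median log2 ratio of pup 3 to pup 1 was -1.06, at percentile 0.18 of level-matched random lists. The pyruvate kinase gene Pkm was at 1154 and 504 TPM and the aldolase gene Aldoa at 857 and 579 TPM, whereas Gapdh was level at 1299 ± 8.01 TPM. Eno2, at 171 and 1.05 TPM, and Slc2a3, at 42.9 and 0.70 TPM, were farther apart, and Pgk1 lay the other way at 101 and 333 TPM. The median level of the list goes against this sign, 158 TPM in pup 1 and 333 TPM in pup 3, where Pgk1 is the middle member.

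Ribosomal protein genes were also lower in pup 3, 17 of 22 being higher in pup 1, with a median log2 ratio of -0.50 (percentile 0.49, level percentile 100). Rpl41 was at 3147 ± 605 TPM, Rps19 at 2577 ± 97.9 and Rps14 at 1939 ± 317 TPM, the last being higher in pup 3; these genes have many processed copies that can take reads. For the axon growth list, 12 of 17 members were higher in pup 1 and the median log2 ratio was -0.54 (percentile 1.71). Both calls ended on CPM with TMM factors, at percentiles 6.32 for ribosomal protein genes and 38.5 for axon growth genes, whose median log2 ratio was then -0.19.

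**Figure D3:**
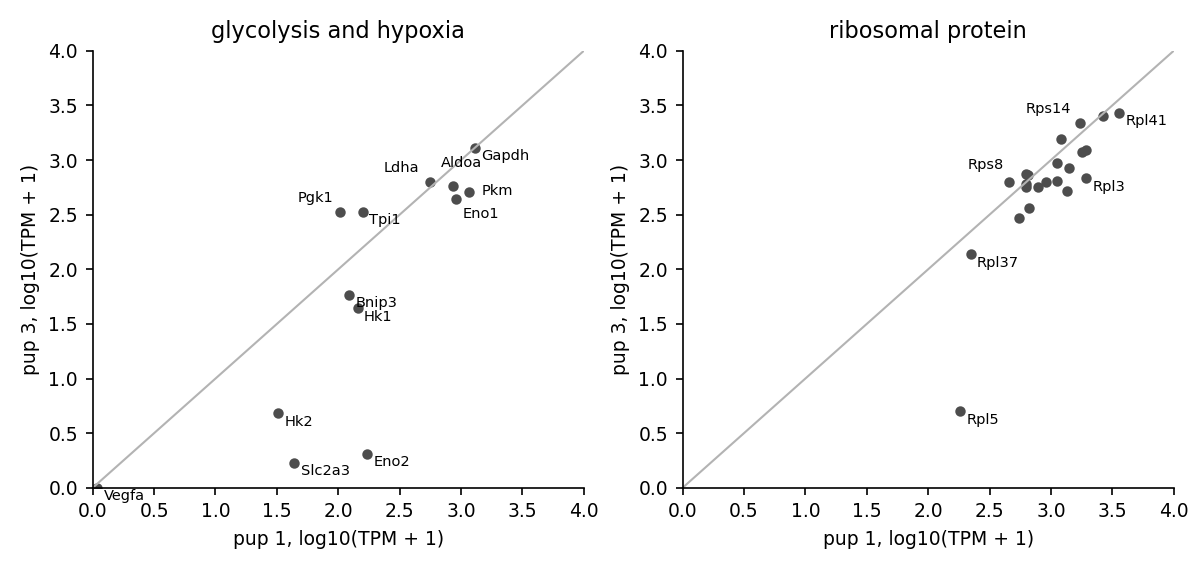
Each point is 1 gene, with log10(TPM + 1) in pup 1 on the x axis and in pup 3 on the y axis. The glycolysis and hypoxia list is on the left and the ribosomal protein list on the right. The line marks equal values. In the glycolysis and hypoxia list 10 of 13 genes, and in the ribosomal protein list 17 of 22, lie on the pup 1 side.

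Listed genes of Cajal-Retzius cells, early neurons of the cortical marginal zone, were found at TPM of 1 or more in pup 1 alone or in neither pup. Of 9 listed genes (level percentile 67.9), 5 were found in pup 1, 0 in pup 3 and 4 in neither. Reln (ENSMUSG00000042453, chromosome 5, 21884454 to 22344702), which encodes reelin, was at 86.3 TPM in pup 1 and 0.02 TPM, 1 read, in pup 3. Ndnf was at 63.7 TPM and Cacna2d2 at 16.3 TPM in pup 1 with 0 reads in pup 3. The list's median log2 ratio was -4.11 over 5 members (percentile 1.34). Level-matched random lists had a median of -2.46, with a central 95% from -4.07 to 1.57. Much of the drop was thus shared by other genes of that level, and the list lay just outside. As a plain ratio without the pseudocount, with 0 reads set to 3 reads, the list's median was -9.03 or lower. The middle member, Cacna2d2, had 0 reads in pup 3. The median was -2.40 on posterior mean TPM and -7.36 with a pseudocount of 0.1, and stayed outside the central 95% under both.

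The signal recognition particle RNA genes Rn7s1 and Rn7s2 were far higher in pup 3, each at 17.3 TPM in pup 1 and 2698 TPM in pup 3; they are near-identical copies whose reads were split equally. Rn7sk was at 50.4 and 164 TPM, and all 4 measured members of the structural RNA list with any reads were higher in pup 3 (median log2 ratio 6.02, percentile 100 against protein-coding genes). Without the pseudocount and with 0 reads set to 3 it was 6.51 or higher, as 1 of the 2 middle members had 0 reads in pup 1. With these copies counted once, an alternative chosen after the data were seen, the median was 4.83 (percentile 100), and with all members it was 4.65 on CPM (percentile 100) and 1.00 on posterior mean TPM (percentile 99.8). The endothelial and mural list lay higher in pup 3 (0.96, percentile 98.7), with 5 members higher in pup 3 and 4 in pup 1; its middle member Cldn5 had reads in both pups, and the median was 0.98 without the pseudocount. Its median level has the opposite sign, 1.08 TPM in pup 1 and 0 TPM in pup 3. The call ended on CPM (97.0), where the median log2 ratio was still 1.01, and on posterior mean TPM (74.1), where it was 0.02. With only members at mean TPM of 1 or more, the median log2 ratio was 1.65. Histone genes (-3.92, percentile 1.18) and long non-coding RNAs (-1.44, percentile 1.17) lay lower in pup 3. Without the pseudocount and with 0 reads set to 3, they were at -5.73 or lower, the middle histone gene having 0 reads in pup 3, and at -1.64. The median level of the long non-coding list has the opposite sign, 106 TPM in pup 1 and 120.1 TPM in pup 3. The histone call ended on CPM (-2.57, percentile 19.1), on posterior mean TPM (-0.07, percentile 33.0) and with length matching (6.02), and its median was -7.15 with a pseudocount of 0.1. The long non-coding call ended with a pseudocount of 0.1 (3.45), on CPM (4.64) and with length matching (4.36). In all, 8 of 31 lists lay outside the central 95% of matched lists, against 1.55 expected if members of a list varied independently. Members of a list can vary together within a library, so this excess cannot be read as more than chance. The other 23 ranged from percentile 2.81 for presynaptic genes to 92.7 for erythroid genes. Of these 23, 3 lay outside under 1 alternative each: cell cycle genes with only members at mean TPM of 1 or more (from -0.69, percentile 31.1, to -2.97, percentile 1.62), telencephalic transcription factors on posterior mean TPM (from -2.70, percentile 3.41, to -1.60, percentile 1.1) and mitochondrially encoded genes on CPM (from 0.35, percentile 84.7, to 0.40, percentile 97.9).

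The sex of the pups was not recorded in the labels. Y-linked transcripts were found in pup 1: Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629) at 13.1 TPM from 1440 reads, Eif2s3y at 25.8 TPM from 1190 reads and Kdm5d at 10.6 TPM from 507 reads, each with 0 reads in pup 3. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the RNA that coats the inactive X chromosome, had 0 reads in pup 1 and 1651 reads, 4.03 TPM, in pup 3. Tsix, which overlaps Xist on the opposite strand, had 9.88 TPM in pup 3 and 0 reads in pup 1; the strand handling of the counting is not given, so the pair cannot be separated. The X-linked copies Eif2s3x (124 ± 59.2), Ddx3x (82.9 ± 44.8) and Kdm5c (23.5 ± 1.86 TPM) were found in both pups. Reads of Kdm5c were farther apart than its TPM, 1047 in pup 1 and 3074 in pup 3. Uty had 0 reads in both pups and Kdm6a 1 read in pup 1. The sex chromosome list was at level percentile 82.9 and difference percentile 83.6.

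**Figure D4:**
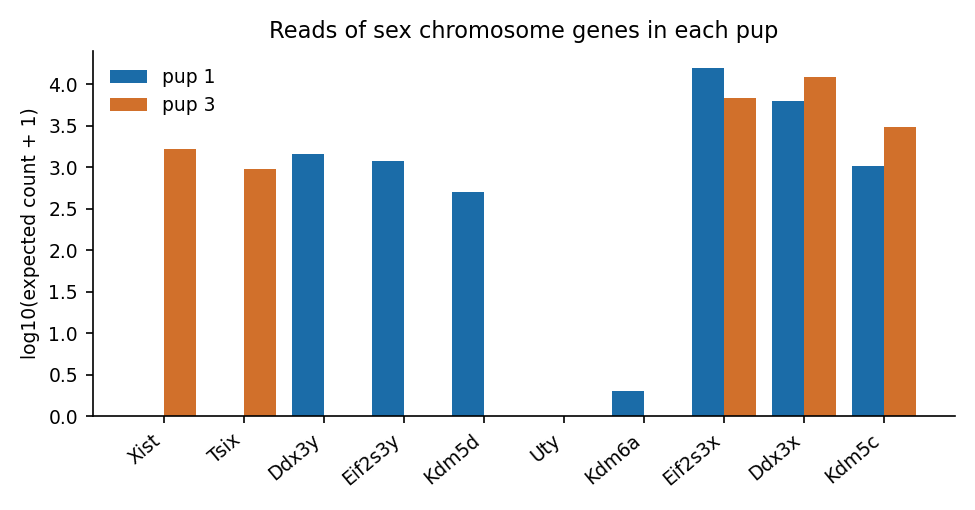
Expected counts of the sex chromosome genes as log10(count + 1) on the y axis, for pup 1 and pup 3. Ddx3y, Eif2s3y and Kdm5d have bars in pup 1 alone, and Xist and Tsix in pup 3 alone.

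Of 20 genes with known alternative exons and mean TPM of 20 or more, 16 had more than 1 listed transcript and were found in both pups, and 13 of these 16 had the same leading annotated isoform in both. Pkm-202 held 85.8% and 88.8% of Pkm, Ncam1-204 88.8% and 95.2% of Ncam1, and the leading isoforms of Snap25 and Cdc42 held 69.1% and 83.9%, and 74.2% and 66.7%. By share of expected counts, the mean share of the leading isoform was 87.6% for Snap25, 75.2% for Mapt, 61.7% for Cdc42, 59.8% for Map2 and 37.4% for Rtn4. The AMPA receptor gene Gria2 kept Gria2-202 first at 39.6% and 96.6%. The leading isoform differed for the other 3, including Dnm1 and Macf1. Dnm1-206, which is annotated as a nonsense-mediated decay transcript, held 43.2% of Dnm1 in pup 1 and 97.6% in pup 3. In pup 1 Dnm1-211 led with 54.2%. Macf1-207 held 50.6% and 31.9% of Macf1. In pup 3 Macf1-210 led with 35.2%, close to the share of Macf1-207, so that change of leader rests on a narrow margin. Tpm1 had 0.12 TPM in pup 3, too little to compare, and App, Dpysl2 and Ptbp2 have 1 listed transcript each, so these 4 were left out.

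Of 96 listed ERCC spike-ins, synthetic RNAs used as internal standards, 39 had reads in pup 1 and 33 in pup 3, with 26 in both. They took 2.08% of the expected counts in pup 1 (2.08 to 2.09, exact binomial interval) and 4.09% in pup 3 (4.09 to 4.10). The most abundant, ERCC-00074, was at 13382 TPM in pup 1 and 21642 TPM in pup 3. All 23 spike-ins at mean TPM of 50 or more were higher in pup 3, at a median ratio of 1.64 (quartiles 1.28 to 1.90). Across the 46 spike-ins seen, Pearson's r was 0.675 and Spearman's rho 0.795.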

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

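The values for genes found in both pups, the shares found by level in the other pup, and the structural RNA list with near-identical copies counted once were chosen after seeing the data. Counts of genes in each pup, spike-ins seen, leading isoforms shared and lists above random lists stayed within 1.5 times; the last was 15 in each pup alone. Genes in both pups numbered 9176 on posterior mean TPM, which by construction gives genes without reads a value above 0. The percent found in both was 54.2 at TPM 0.1, 50.02 at TPM 5, 54.0 at 5 or more reads, 63.2 on posterior mean TPM, 53.4 for protein-coding genes and 53.9 after thinning pup 1. Pearson's r across genes was 0.461 with a pseudocount of 0.1, 0.412 at mean TPM of 1 or more, 0.589 on FPKM, 0.520 on CPM, 0.761 on posterior mean TPM and 0.530 for protein-coding genes. Spearman's rho was 0.422 at mean TPM of 1 or more, 0.798 on posterior mean TPM and 0.487 for protein-coding genes. The SD of the log2 ratio was 2.54 with a pseudocount of 0.1, 1.60 on FPKM, 2.66 on CPM, 1.95 on posterior mean TPM, 2.17 without spike-ins and mitochondrial genes and 1.44 for genes found in both pups, where 60.2% lay within 2-fold. That percent was 50.4 on CPM and 55.6 without spike-ins and mitochondrial genes. The biological coefficient of variation was 0.856 with 10 or more reads in each library, which by construction removes genes missing from one pup. Spike-in r was 0.470 with a pseudocount of 0.1. Lists apart between pups numbered 4 on CPM, 3 of them shared with the 8 on TPM. For the other changes the cause was not tested. The glycolysis, Cajal-Retzius and structural RNA lists stayed outside the central 95% under the alternatives tried for list differences, and none of the 8 changed sign. Of 223 list levels under alternatives, 204 kept their side of the thresholds, 11 lost it and 8 gained it; of 186 list differences, 173 kept it, 10 lost it and 3 gained it. Of 32 isoform shares, from genes with several transcripts and found in both pups, 27 moved by no more than the SD between pups and 5 by more. Shared leading isoforms, detection, correlation and differences between pups need both libraries, so no value leaves a pup out.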

Other observations

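The tests of spike-in level, detection of the shortest genes, sex-linked reads and genes without reads in pup 3 were chosen after those values were seen; thinning of reads and length matching were planned before the data were examined, but their bounds, and the ratio used for thinning, were set after, while bounds for the difference in detection between short and long genes and for narrow credibility intervals were set before their results.

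More genes were found in pup 1 than in pup 3 (10096 against 6960). Read depth is argued against as the whole cause: with pup 1 thinned to 72.7% of its reads, genes with 5 or more reads still stood at a ratio of 1.44. Loss of long transcripts is argued against as the whole cause by the shortest tertile of protein-coding genes. Of 1373 such genes at 10 to 50 TPM in pup 1, 47.9% were found in pup 3. Of 739 at that level in pup 3, 73.9% were found in pup 1. The sets of genes differ, and each was split by its own lengths, so the same genes are not followed across pups. The gap was 26.0 points (interval 21.8 to 29.8) for the shortest tertile and 28.9 points for the longest. Loss of long transcripts as a part of the cause stays open, the difference of 2.91 points having an interval of -2.40 to 9.00. A smaller amount of forebrain RNA relative to spike-ins in pup 3 is a candidate explanation, with a median spike-in ratio of 1.64, but more spike-in added to pup 3 would give the same ratio, and fewer spike-ins were seen there (33 against 39). No biological explanation was tested.

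Y-linked reads lay in pup 1 and Xist reads in pup 3. Misassigned reads of the X-linked copies are argued against by a relative rate of 0: pup 3 had 22020.5 reads of those copies (22937 in pup 1) and 0 Y-linked reads, which allows up to 0.0136 per 100, against 13.7 per 100 in pup 1. Chance loss stays open for the missing Y-linked reads. Of other protein-coding genes at 10 to 50 TPM in pup 1, 38.7% had 0 reads in pup 3. That is a rate for single genes. Loss of Ddx3y, Eif2s3y and Kdm5d together would be rarer if genes are lost independently, and its rate was not computed. Chance loss also gives no account of the 1651 Xist reads in pup 3. A male pup 1 and a female pup 3 may account for both, as a hypothesis, since the labels record no sex and RNA carried over between samples was not tested.

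The glycolysis and hypoxia list was lower in pup 3 by a median log2 of -1.06. Transcript length is argued against as the whole cause, the list being at percentile 0.10 of lists matched on level and length. Reads shared with copies stay open. With 12 members and other genes of narrow credibility intervals, the list was at percentile 0.42. That filter left out only Vegfa and read the interval only in the pup where a gene was higher. It nearly repeats the main result, so it cannot decide. Sampling of few molecules, dissection and a difference between the animals stay open, as 1 library per pup cannot separate them, and this list was picked from 31 because it stood farthest below.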
